A study of Homo sapiens with 8 samples.

How the data were processed

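The series holds 8 polyA RNA libraries of H9 human embryonic stem cells in 4 groups of 2, D1_Co (replicates 2 and 3), D2_Co (replicates 1 and 3), D3_Co (replicates 1 and 2) and D3_Control (replicates 2 and 3), with groups, days and replicate numbers taken from the library titles. Per the labels' protocols, human pluripotent cells were grown on Matrigel in mTeSR1 medium, or on mitotically inactivated mouse fibroblast feeders in a medium with FGF2 and the WNT inhibitor IWR1. Which of these applied to which library is not given in the sources used here. RNA was extracted with a column kit with DNase treatment, per the labels' protocols. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.3b and the genome build GRCh38.p12, without settings.

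The authors deposited 1 table of gene-level FPKM, with 45961 gene numbers, a name for each and 8 value columns. All columns were used. The values are not counts, so limma was used and no count test was run. FPKM divides by the fragments mapped in a library, which the table does not give. The smallest values gave rough relative depths of 0.888 to 1.32 against 1 for D3_Control replicate 2, but only 13% to 16.3% of values lay at the most common step, so no reads were recovered and absolute depth is unknown. No intervals that need read numbers were therefore given.

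In the table as deposited, many values did not stand on the row of their own gene. ACTB, the beta-actin gene, was listed at 0 in 7 libraries and at 7523 FPKM in D1_Co replicate 2, and within-group correlations lay between 0.825 and 0.893. The order of the rows fitted a simple history, in which each library's lines of gene number and value were sorted as text without the separator, pasted beside the gene numbers of D1_Co replicate 2 and sorted again by gene number. Under that history 3394 gene numbers, those that begin a longer number, can trade places. For each of the other 7 libraries an exact dynamic-programming search took the order that this history allows and that lies closest to D1_Co replicate 2, with the absolute log2 difference per row capped at 4. All 7 libraries had an allowed order and sorted back exactly to the 45961 rows deposited, while each of the 2 control rules was impossible in 7 of 7. After realignment ACTB lay between 5852 and 7930 FPKM in all libraries, and within-group correlations between 0.992 and 0.994. The criterion itself raises both values, so they are no test of the search. All libraries are drawn to the same reference, so differences between any groups, D3_Co against D3_Control included, can be understated on rows that moved.

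Of 13104 rows with a mean of at least 1 FPKM over the 8 libraries, 12449 carried a name that is the symbol or a synonym of their gene number in a RefSeq gene table and were tested. The other 655 rows, which held 3.93% to 4.43% of FPKM, were left out. Over all rows, 43963 gene numbers were in the RefSeq table and 36028 matched by name. Of the tested rows, 7964 had stayed in place in all libraries and 4485 had a value moved in at least 1. The search was repeated under 10 random changes of the reference (SD 0.5 on the log2 scale), and 552 rows whose values then differed by over 0.25 were marked as unsettled. On simulated data sorted by the same history, 3517 of 13255 rows had a misplaced value before the search and 50 after it, of which 29 were marked as unsettled. All simulated libraries were drawn around a common mean of each gene, and only 200 genes were changed, all in D3_Co. The groups measured here differ at many more genes, so recovery on these data can be lower.

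limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with all 8 libraries in 1 model of 4 groups (4 residual and 3.19 prior degrees of freedom, eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg, with calls under 0.05. On data simulated for D3_Co against D3_Control over 12575 genes, 49 of 49 genes changed by -2 on the log2 scale and 50 of 50 at each of -1, 1 and 2 were called, as were 28 of 12376 unchanged genes. Their median fitted differences were -1.56, -0.83, 0.93 and 1.84, smaller than those put in. 6 comparisons were made, D3_Co, D1_Co and D2_Co each against D3_Control, and the 3 between co-culture days. Overlaps among the comparisons with D3_Control were set beside 100 simulations of unchanged groups, in which all 8 libraries were redrawn around the D3_Control mean of each gene, and, chosen after the result was seen, beside fits with split controls.

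Before the data were examined, 36 gene lists were fixed, as were the rule for named genes and the alternatives. 33 lists with at least 5 measured genes were tested with camera (preset correlation 0.01) and fry. Mitochondrially encoded mRNAs (0 genes), amnion and trophoblast (4 genes) and haematopoietic markers (2 genes) were too small, since the table or the filter left few. With a correlation estimated from the data, 0 lists were called in any comparison, and camera's calls therefore hold with the preset correlation only. fry, which tests whether a list moves on balance and does not compare it with other genes, called 19 of those 19 lists in D3_Co against D3_Control, 19 of 19 in D1_Co and 22 of 22 in D2_Co against D3_Control, 12 of 12 in D2_Co against D1_Co, 13 of 14 in D3_Co against D2_Co (not G1/S and DNA replication, fry adjusted p = 0.127) and 16 of 17 in D3_Co against D1_Co (not cytosolic ribosomal proteins, 0.0999). The rule named the 10 called genes with the largest rise and the 10 with the largest fall for D3_Co against D3_Control (5 and 5 elsewhere) among those whose groups do not overlap, up to 4 genes with the smallest p of each called list, and 15 genes in any case. Of these 15, BCL2 (mean 0.745 FPKM) and COL3A1 (mean 0.0101 FPKM) did not pass the filter. Outside D3_Co against D3_Control the text describes only part of the lists called, which numbered 19 in D1_Co against D3_Control (15 higher and 4 lower), 22 in D2_Co against D3_Control (15 and 7), 12 in D2_Co against D1_Co (6 and 6), 14 in D3_Co against D2_Co (6 and 8) and 17 in D3_Co against D1_Co (6 and 11). The text gives only part of the genes so named, some are not reported here, short RNAs were left out, and some whose calls were lost in most fits without 1 library were passed over, among them FOS, S100A6 and MIR3064 in D2_Co against D1_Co and CDRT4 and TVP23C-CDRT4 in D3_Co against D3_Control and against D2_Co.

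Positions are those of whole genes in GENCODE release 29 on GRCh38, which placed 271 of 272 genes, and each value sums over a gene's exons as the authors' annotation defined them. Whether strand was used in counting is not given in the sources used here, so genes that overlap others are uncertain. Alternatives were another pseudocount (0.1), no filter or a mean of at least 5 FPKM, median-of-ratios and quantile scaling, a fit of the 4 libraries alone, eBayes without a trend, a replicate block, at least 2-fold, an estimated correlation and leaving out each library. 5 more were chosen after seeing the data, namely the table as deposited, another reference, unsettled rows left out, only rows in place, and rows with unmatched names included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the search and the figures.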

Results

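Messenger RNA of H9 cells, an established human embryonic stem cell line, was measured in 8 polyA libraries. The library titles name 4 groups of 2. In 3 of them, D1_Co, D2_Co and D3_Co, the title carries the word Co, read here as co-culture of days 1, 2 and 3. The remaining group, D3_Control, is read as separate culture of day 3. The labels name neither the partner cells nor how human cells were set apart from them before RNA was taken. The series is about cell competition as a barrier to chimeras between species. The comparisons below ask how transcript levels of the human cells in co-culture differed from those in separate culture, and how they moved over the days. Values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) after returning misplaced values to their genes, and 12449 genes were tested. All groups hold n = 2 libraries and errors are SDs of FPKM. Log2 differences are on the log2(FPKM + 1) scale, which understates changes of low genes. Members of a list are counted with p adjusted over all genes, then with p adjusted over the list alone, and medians of lists are of log2 differences. Genes whose exons are said to overlap others have uncertain values. Statements on lists rest on camera, and in the comparisons other than D3_Co against D3_Control many of these counts shrink without 1 library. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these samples. FPKM summed to between 421825 and 440675 per library, and the number of reads behind them is unknown.

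Libraries of a group lay closest to each other. The mean correlation across genes was 0.992 within groups, and between groups it was highest for D1_Co with D2_Co (0.987) and lowest for D2_Co with D3_Control (0.976). Genes are not independent replicates, and these values describe the libraries only. The leading principal components held 37.7% and 24.5% of the variance. POU5F1, a transcription factor of the pluripotent state, lay at 795 ± 22.4 against 746 ± 33.5 FPKM in D3_Co and D3_Control. Exons of POU5F1 overlap other genes.

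D3_Co against D3_Control, matched by day, asks what differed between co-culture and separate culture on day 3. Targets of NF-kB, a transcription factor of inflammatory signalling, were higher in co-culture, and genes of ribosome biogenesis and DNA replication were lower. PLAU, the urokinase protease, lay at 128 ± 10.2 FPKM against 26.7 ± 3.13 FPKM (log2 difference 2.23, SE 0.10, adjusted p = 8.34e-05). IL32, an inflammatory cytokine, lay at 16.3 ± 0.768 FPKM against 2.85 ± 0.0221 FPKM (log2 difference 2.17, SE 0.15, adjusted p = 0.000307). FOXD3, a transcription factor of primed pluripotent cells, lay at 3.09 ± 0.0247 FPKM against 11.9 ± 0.817 FPKM (log2 difference -1.66, SE 0.11, adjusted p = 0.000243). limma with Benjamini-Hochberg adjustment called 3032 of 12449 genes, 1684 higher and 1348 lower, of which 150 differed by over 2-fold. The split turned to 1513 higher and 1522 lower with median-of-ratios scaling and to 1099 and 1267 with a mean of at least 5 FPKM. Leaving out D3_Co replicate 1, D3_Co replicate 2, D3_Control replicate 2 or D3_Control replicate 3 left 1849, 1679, 1618 and 1603 genes called. Exons of IL32 overlap other genes.

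22 of 32 NF-kB targets rose and 0 fell, or 24 and 1 adjusted over the list alone, with NFKB2, a subunit of NF-kB itself, at 1.46. NF-kB targets were called higher (median 0.74, camera adjusted p = 6.12e-12, adjusted p = 0.110 with an estimated correlation). CXCL5 and CXCL1, chemokines, rose by 1.75 and 2.08 on the log2 scale. The list of upstream components did not pass. 2 of 19 TLR, MyD88 and NF-kB signalling components rose and 1 fell, or 2 and 1 adjusted over the list alone. TLR, MyD88 and NF-kB signalling components were not called (median 0.07, camera adjusted p = 0.646, adjusted p = 0.735 with an estimated correlation). MYD88 was called lower (-0.24, adjusted p = 0.0254), and RELA had a difference of 0.01 (adjusted p = 0.908). 17 of 20 immediate early genes rose and 0 fell, or 19 and 0 adjusted over the list alone, with NR4A1, a nuclear receptor, at 5.37 ± 0.551 against 1.695 ± 0.0581 FPKM. Immediate early genes were called higher (median 0.70, camera adjusted p = 9.21e-11, adjusted p = 0.110 with an estimated correlation). 9 of 19 interferon-response genes rose and 0 fell, or 10 and 2 adjusted over the list alone. Interferon-response genes were called higher (median 0.29, camera adjusted p = 0.000377, adjusted p = 0.110 with an estimated correlation). 9 of 15 MHC class I genes rose and 1 fell, or 9 and 2 adjusted over the list alone, with HLA-B at 42.4 ± 1.73 against 23.9 ± 0.863 FPKM. MHC class I genes were called higher (median 0.37, camera adjusted p = 0.00162, adjusted p = 0.110 with an estimated correlation). Fibroblast markers moved in the same direction as these groups, and 6 of them are also on the mesenchymal list. 14 of 24 fibroblast markers rose and 1 fell, or 15 and 1 adjusted over the list alone, with COL1A1, a fibrillar collagen, at 41.2 ± 1.81 against 28.2 ± 0.8497 FPKM. Fibroblast markers were called higher (median 0.35, camera adjusted p = 2.66e-06, adjusted p = 0.110 with an estimated correlation). COL3A1, DCN and LUM, abundant in fibroblasts, stayed at or below 0.0087 FPKM in the co-culture libraries. MYD88 lost its call without D3_Co replicate 1 (adjusted p = 0.114), D3_Co replicate 2 (0.0537), D3_Control replicate 2 (0.114) and D3_Control replicate 3 (0.0782). Of the TLR, MyD88 and NF-kB signalling components, 2 that rose became 0 without D3_Co replicates 1 or 2 or D3_Control replicates 2 or 3. Exons of COL3A1, HLA-B, NR4A1 and RELA overlap other genes.

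Genes of cell shape and attachment were higher on day 3, beside the fibroblast markers above. 15 of 22 mesenchymal and EMT genes rose and 1 fell, or 17 and 1 adjusted over the list alone. Mesenchymal and EMT genes were called higher (median 0.47, camera adjusted p = 7.68e-08, adjusted p = 0.110 with an estimated correlation). 12 of 25 adhesion, integrin and basement membrane genes rose and 1 fell, or 14 and 2 adjusted over the list alone, with the integrin subunits ITGA3 and ITGAV at 0.85 and 0.89. Adhesion, integrin and basement membrane genes were called higher (median 0.26, camera adjusted p = 0.000158, adjusted p = 0.110 with an estimated correlation). YAP and TEAD respond to cell contact and tension. 10 of 21 YAP and TEAD targets rose and 1 fell, or 10 and 1 adjusted over the list alone, with CCN1 at 147 ± 1.53 against 101 ± 5.93 FPKM. YAP and TEAD targets were called higher (median 0.26, camera adjusted p = 0.00107, adjusted p = 0.149 with an estimated correlation). 10 of 29 epithelial and tight junction genes rose and 2 fell, or 11 and 2 adjusted over the list alone, with CLDN4, a claudin, at 8.34 ± 0.924 against 2.49 ± 0.126 FPKM. Epithelial and tight junction genes were called higher (median 0.07, camera adjusted p = 0.0346, adjusted p = 0.134 with an estimated correlation). 11 of 28 cholesterol synthesis genes rose and 3 fell, or 12 and 3 adjusted over the list alone, with the enzyme MSMO1 at 0.47. Cholesterol synthesis genes were called higher (median 0.15, camera adjusted p = 0.0195, adjusted p = 0.427 with an estimated correlation). Epithelial and tight junction genes lost their call without D3_Co replicate 1 (adjusted p = 0.0869) and D3_Control replicate 3 (0.121) and with only rows in place (0.187). Cholesterol synthesis genes lost their call without D3_Co replicate 1 (adjusted p = 0.0501) and D3_Control replicate 3 (0.0735) and with only rows in place (0.0528). Of the cholesterol synthesis genes, 11 that rose became 6 without D3_Co replicate 1, 5 without D3_Co replicate 2 and 4 without D3_Control replicates 2 or 3. Exons of ITGAV overlap other genes.

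Stress genes were higher and heat shock genes lower. 20 of 33 integrated stress and unfolded protein response genes rose and 2 fell, or 22 and 5 adjusted over the list alone, with CHAC1, a target of the stress factor ATF4, at 37.9 ± 2.71 against 14.7 ± 0.875 FPKM. Integrated stress and unfolded protein response genes were called higher (median 0.39, camera adjusted p = 1.59e-06, adjusted p = 0.110 with an estimated correlation). 16 of 35 p53 targets rose and 0 fell, or 22 and 2 adjusted over the list alone, with GDF15, a secreted stress protein, at 35.2 ± 1.83 against 12.1 ± 0.159 FPKM. The p53 targets were called higher (median 0.19, camera adjusted p = 4.17e-06, adjusted p = 0.110 with an estimated correlation). MDM2, a ubiquitin ligase, rose by 0.24. CDKN1A, a cell cycle inhibitor, had a difference of 0.59 (adjusted p = 0.007096) on a row not settled in the realignment. 13 of 31 glycolysis and hypoxia genes rose and 3 fell, or 13 and 3 adjusted over the list alone, with DDIT4, an inhibitor of mTOR, at 33.4 ± 2.78 against 7.65 ± 0.0708 FPKM. Glycolysis and hypoxia genes were called higher (median 0.15, camera adjusted p = 0.00306, adjusted p = 0.110 with an estimated correlation). 1 of 17 heat shock genes rose and 7 fell, or 2 and 9 adjusted over the list alone, with the chaperone HSPA8 at 1005 ± 15.6 against 1538 ± 23.7 FPKM. Heat shock genes were called lower (median -0.14, camera adjusted p = 0.00475, adjusted p = 0.221 with an estimated correlation). BCL2L1, an inhibitor of apoptosis on an unsettled row, had a difference of 0.13 (adjusted p = 0.269). 6 of 24 pro-apoptotic genes rose and 3 fell, or 7 and 5 adjusted over the list alone. Pro-apoptotic genes were not called (median 0.15, camera adjusted p = 0.208, adjusted p = 0.398 with an estimated correlation). 1 of 12 anti-apoptotic genes rose and 0 fell, or 0 and 0 adjusted over the list alone. Anti-apoptotic genes were not called (median 0.08, camera adjusted p = 0.646, adjusted p = 0.812 with an estimated correlation). MDM2 lost its call without D3_Co replicate 2 (adjusted p = 0.0777), D3_Control replicate 2 (0.0547) and D3_Control replicate 3 (0.0839). The glycolysis and hypoxia genes lost their call with only rows in place (adjusted p = 0.0616). The heat shock genes lost their call with only rows in place (adjusted p = 0.0891). Of the glycolysis and hypoxia genes, 13 that rose became 7 without D3_Co replicate 2 or D3_Control replicate 3. Of the heat shock genes, 7 that fell became 4 without D3_Co replicate 2 or D3_Control replicates 2 or 3. Of the anti-apoptotic genes, 1 that rose became 0 without D3_Co replicates 1 or 2 or D3_Control replicate 3. Exons of BCL2L1, CDKN1A, DDIT4, HSPA8 and MDM2 overlap other genes.

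Other lists were lower on day 3. 0 of 38 MYC targets and ribosome biogenesis genes rose and 28 fell, or 0 and 29 adjusted over the list alone, with RRP9, a factor of ribosomal RNA processing, at 28.6 ± 1.46 against 43.4 ± 1.13 FPKM. MYC targets and ribosome biogenesis genes were called lower (median -0.34, camera adjusted p = 8.83e-12, adjusted p = 0.0847 with an estimated correlation). MYCN, a MYC family member, lay at 13.2 ± 0.604 FPKM against 26.7 ± 1.305 FPKM (log2 difference -0.97, SE 0.08, adjusted p = 0.000634), and MYC had a difference of -0.09 (adjusted p = 0.325). 0 of 38 G1/S and DNA replication genes rose and 20 fell, or 0 and 22 adjusted over the list alone, with the replicative helicase subunits MCM5 and MCM2 at -0.44 and -0.55. G1/S and DNA replication genes were called lower (median -0.22, camera adjusted p = 7.25e-08, adjusted p = 0.131 with an estimated correlation). 0 of 42 nuclear-encoded oxidative phosphorylation genes rose and 6 fell, or 0 and 1 adjusted over the list alone, with NDUFS3 at -0.41. Nuclear-encoded oxidative phosphorylation genes were called lower (median -0.08, camera adjusted p = 0.0307, adjusted p = 0.162 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes lost their call without D3_Co replicate 2 (adjusted p = 0.0526) and D3_Control replicate 2 (0.0789) and with a mean of at least 5 FPKM (0.1498), quantile normalization (0.401) and only rows in place (0.186). Of the G1/S and DNA replication genes, 20 that fell became 13 without D3_Co replicate 1 and 11 without D3_Co replicate 2 or D3_Control replicates 2 or 3. Of the nuclear-encoded oxidative phosphorylation genes, 6 that fell became 3 without D2_Co replicates 1 or 3 or D3_Control replicate 3 and 2 without D3_Co replicates 1 or 2 or D3_Control replicate 2. Exons of MCM2, MYCN and NDUFS3 overlap other genes.

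Primed pluripotency genes were lower and naive ones higher. 1 of 30 primed and core pluripotency genes rose and 15 fell, or 2 and 15 adjusted over the list alone, with DNMT3B, a DNA methyltransferase, at 412 ± 11.8 against 657 ± 7.83 FPKM. Primed and core pluripotency genes were called lower (median -0.27, camera adjusted p = 3.31e-05, adjusted p = 0.110 with an estimated correlation). SOX2 (-0.11, adjusted p = 0.1899), NANOG (-0.11, adjusted p = 0.2004) and POU5F1 (0.09, adjusted p = 0.233) did not pass. 4 of 8 naive pluripotency genes rose and 0 fell, or 5 and 0 adjusted over the list alone, with KLF5, TFAP2C, NODAL and SUSD2 at 1.05, 0.85, 0.22 and 0.29. Naive pluripotency genes were called higher (median 0.26, camera adjusted p = 0.00540, adjusted p = 0.110 with an estimated correlation). NODAL, also on the NODAL and activin list, lost its call without D3_Co replicate 2, D3_Control replicate 2 or D3_Control replicate 3. SUSD2 lost its call in each fit without 1 library. Of the naive pluripotency genes, 4 that rose became 2 without D3_Co replicate 2 or D3_Control replicates 2 or 3. Exons of NODAL overlap other genes.

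The remaining lists did not pass camera on day 3. Cell competition is the theme of the series. 4 of 31 genes linked to cell competition rose and 3 fell, or 5 and 3 adjusted over the list alone. Genes linked to cell competition were not called (median 0.03, camera adjusted p = 0.833, adjusted p = 0.846 with an estimated correlation). 0 of 45 cytosolic ribosomal protein genes rose and 0 fell, or 0 and 0 adjusted over the list alone. Cytosolic ribosomal protein genes were not called (median 0.02, camera adjusted p = 0.682, adjusted p = 0.867 with an estimated correlation). 4 of 35 G2/M and mitosis genes rose and 3 fell, or 3 and 3 adjusted over the list alone. G2/M and mitosis genes were not called (median 0.04, camera adjusted p = 0.682, adjusted p = 0.758 with an estimated correlation). 4 of 11 WNT and beta-catenin targets rose and 1 fell, or 4 and 1 adjusted over the list alone. WNT and beta-catenin targets were not called (median -0.02, camera adjusted p = 0.646, adjusted p = 0.758 with an estimated correlation). 4 of 19 NODAL and activin targets rose and 6 fell, or 6 and 8 adjusted over the list alone. NODAL and activin targets were not called (median -0.13, camera adjusted p = 0.361, adjusted p = 0.622 with an estimated correlation). 1 of 9 BMP targets rose and 3 fell, or 1 and 4 adjusted over the list alone. BMP targets were not called (median -0.06, camera adjusted p = 0.646, adjusted p = 0.812 with an estimated correlation). Of the G2/M and mitosis genes, 4 that rose became 1 without D3_Co replicates 1 or 2 or D3_Control replicate 3 and 2 without D3_Control replicate 2. Of the WNT and beta-catenin targets, 4 that rose became 1 without D3_Co replicate 1 or D3_Control replicate 3 and 2 without D3_Co replicate 2 or D3_Control replicate 2. Of the BMP targets, 3 that fell became 1 without D3_Co replicate 2 and 0 without D3_Control replicate 2.

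Lineage, ERK and RNA composition lists did not pass camera on day 3 either. 7 of 23 FGF and ERK targets rose and 4 fell, or 8 and 4 adjusted over the list alone. FGF and ERK targets were not called (median -0.01, camera adjusted p = 0.646, adjusted p = 0.812 with an estimated correlation). 3 of 9 neuroectoderm genes rose and 2 fell, or 3 and 3 adjusted over the list alone. Neuroectoderm genes were not called (median -0.06, camera adjusted p = 0.883, adjusted p = 0.904 with an estimated correlation). 3 of 7 mesendoderm and endoderm genes rose and 1 fell, or 3 and 1 adjusted over the list alone. Mesendoderm and endoderm genes were not called (median 0.22, camera adjusted p = 0.263, adjusted p = 0.437 with an estimated correlation). 1 of 10 replication-dependent histone genes rose and 2 fell, or 1 and 4 adjusted over the list alone. Replication-dependent histone genes were not called (median -0.29, camera adjusted p = 0.164, adjusted p = 0.279 with an estimated correlation). 1 of 14 long non-coding and host RNAs rose and 0 fell, or 1 and 0 adjusted over the list alone. Long non-coding and host RNAs were not called (median 0.04, camera adjusted p = 0.816, adjusted p = 0.845 with an estimated correlation). Of the neuroectoderm genes, 3 that rose became 1 without D3_Co replicate 1 or D3_Control replicate 3. Of the mesendoderm and endoderm genes, 3 that rose became 1 without D3_Co replicate 1. Of the long non-coding and host RNAs, 1 that rose became 2 without D3_Co replicate 1.

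The largest rise was that of WNT10B, a secreted WNT ligand (gene 7480, chromosome 12, 48965340 to 48971763), at 5.46 ± 0.0548 FPKM against 0.2302 ± 0.0293 FPKM (log2 difference 2.39, SE 0.07, adjusted p = 2.22e-05). GARIN1B (gene 84691, chromosome 7, 128709061 to 128731743) rose by 2.29, and CH25H, the cholesterol 25-hydroxylase (gene 9023, chromosome 10, 89205629 to 89207314), by 2.22. ZC3H12A, a ribonuclease that limits inflammatory transcripts (gene 80149, chromosome 1, 37474552 to 37484379), rose by 2.14, and PIK3CD (gene 5293, chromosome 1, 9651732 to 9729114) by 2.05. PLAU (gene 5328, chromosome 10, 73909177 to 73917497), IL32 (gene 9235, chromosome 16, 3065297 to 3082192) and CXCL1 (gene 2919, chromosome 4, 73869393 to 73871242) were also among the largest. PLAU, PIK3CD and FOXD3 (gene 27022, chromosome 1, 63323041 to 63325126) overlap genes of the other strand, as does COX11, a factor of cytochrome oxidase assembly (gene 1353, chromosome 17, 54951902 to 54968785), at -1.54, so their values are uncertain. IQSEC2 (gene 23096, chromosome X, 53225828 to 53321350) had a difference of -1.67, and LRAT, a retinol-esterifying enzyme (gene 9227, chromosome 4, 154626945 to 154753118), one of -1.35. Metallothioneins, zinc-binding proteins, were lower, with MT1E (gene 4493, chromosome 16, 56625475 to 56627112) at 14.6 ± 1.76 against 40.9 ± 0.237 FPKM and MT1G (gene 4495, chromosome 16, 56666731 to 56668065) at 14.2 ± 1.25 against 39.6 ± 6.76 FPKM. MT1H (gene 4496, chromosome 16, 56669814 to 56671129) lay at 2.47 ± 0.376 against 7.92 ± 0.987 FPKM. Metallothioneins are near-identical copies of each other, so single members are uncertain. SFRP1, a WNT antagonist, had a difference of -1.38 on an unsettled row. MT1H lost its call without D3_Co replicate 1 (adjusted p = 0.0561) and D3_Control replicate 2 (0.0629). Exons of ZC3H12A overlap other genes.

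**Figure D1:**
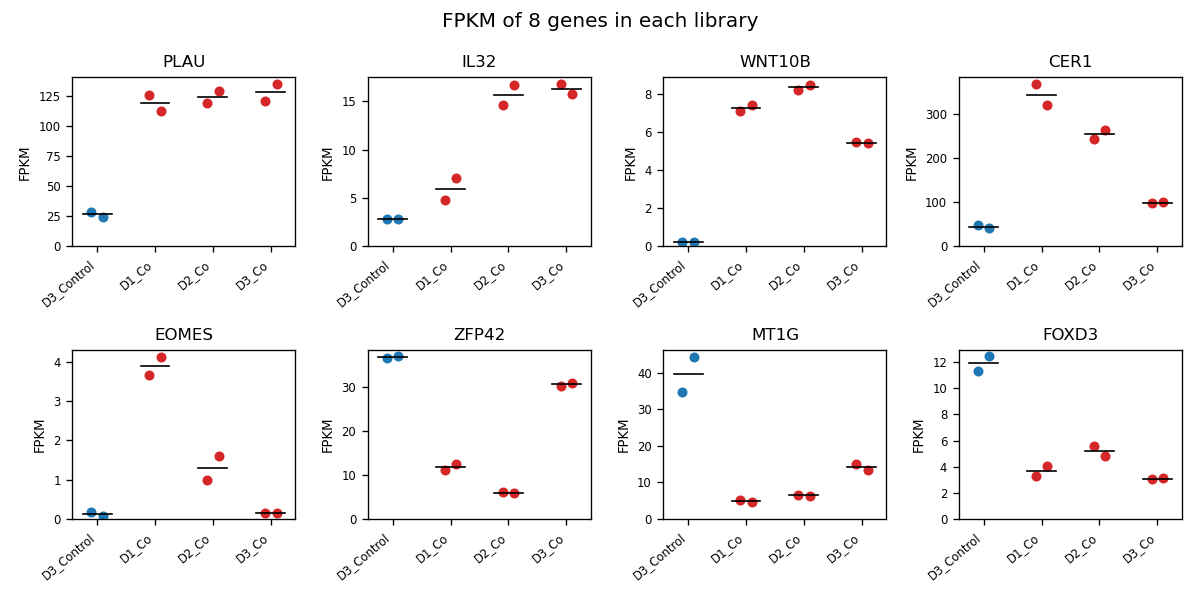
FPKM (vertical axes, linear, from 0) of PLAU, IL32, WNT10B, CER1, EOMES, ZFP42, MT1G and FOXD3 in the 4 groups (horizontal axes), where each point is a library and each line the mean of its group of n = 2. PLAU lies at 128 FPKM in D3_Co and 26.7 FPKM in D3_Control, and CER1 at 343 FPKM in D1_Co, 253 FPKM in D2_Co, 98.9 FPKM in D3_Co and 44.9 FPKM in D3_Control.

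D1_Co against D3_Control sets day 1 of co-culture beside separate culture of day 3, so culture and day differ together. Several genes of the early mesendoderm, the precursor of mesoderm and endoderm, were high on day 1. CER1, a secreted NODAL antagonist (gene 9350, chromosome 9, 14719724 to 14722717), lay at 343 ± 33.1 FPKM against 44.9 ± 5.21 FPKM (log2 difference 2.91, SE 0.10, adjusted p = 2.47e-05). FGF17, a growth factor (gene 8822, chromosome 8, 22042398 to 22048809), lay at 6.41 ± 0.718 against 0.0611 ± 0.0864 FPKM, and SP5, a target of WNT signalling (gene 389058, chromosome 2, 170715351 to 170718078), at 7.14 ± 0.654 against 0.203 ± 0.0699 FPKM. MT1G lay at 4.902 ± 0.315 FPKM against 39.6 ± 6.76 FPKM (log2 difference -2.77, SE 0.12, adjusted p = 3.24e-05). limma called 2835 genes, 1311 higher and 1524 lower, with 228 over 2-fold. The split turned to 1638 higher and 1070 lower with median-of-ratios scaling and to 1333 and 1296 with quantile normalization. Without D1_Co replicate 2, D3_Control replicate 2 or D3_Control replicate 3, 1501, 1724 and 1355 genes were called, and the split turned as well (758 higher and 743 lower, 890 and 834, 730 and 625).

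7 of 23 mesendoderm and endoderm genes were tested, by a filter that can favour genes high in 1 group. 5 rose and 1 fell, or 5 and 1 adjusted over the list alone. EOMES, a T-box factor of the primitive streak, lay at 3.89 ± 0.315 against 0.126 ± 0.0757 FPKM. The list was called higher (median 1.32, camera adjusted p = 4.43e-05, adjusted p = 0.0925 with an estimated correlation). 10 of 19 NODAL and activin targets rose and 4 fell, or 12 and 5 adjusted over the list alone, with NODAL itself at 56.2 ± 0.779 against 29.1 ± 0.294 FPKM. NODAL and activin targets were called higher (median 0.49, camera adjusted p = 0.000576, adjusted p = 0.139 with an estimated correlation). 5 of 9 BMP targets rose and 0 fell, or 5 and 0 adjusted over the list alone, with ID1 and ID2, inhibitors of differentiation, at 0.53 and 0.74. BMP targets were called higher (median 0.29, camera adjusted p = 9.3e-05, adjusted p = 0.132 with an estimated correlation). 18 of 32 NF-kB targets rose and 0 fell, or 20 and 0 adjusted over the list alone, with PLAU at 119.7 ± 9.53 against 26.7 ± 3.13 FPKM. NF-kB targets were called higher (median 0.49, camera adjusted p = 3.84e-11, adjusted p = 0.0925 with an estimated correlation). 11 of 21 YAP and TEAD targets rose and 0 fell, or 12 and 0 adjusted over the list alone. YAP and TEAD targets were called higher (median 0.29, camera adjusted p = 9.52e-09, adjusted p = 0.0925 with an estimated correlation). 25 of 33 integrated stress and unfolded protein response genes rose and 0 fell, or 25 and 2 adjusted over the list alone, with TRIB3, an ATF4 target, at 23.2 ± 0.266 against 7.49 ± 0.669 FPKM. The list was called higher (median 0.51, camera adjusted p = 1.57e-13, adjusted p = 0.0925 with an estimated correlation). 13 of 22 mesenchymal and EMT genes rose and 0 fell, or 16 and 0 adjusted over the list alone, with VIM, vimentin, at 1118 ± 116 against 481 ± 86.1 FPKM. Mesenchymal and EMT genes were called higher (median 0.42, camera adjusted p = 7.64e-10, adjusted p = 0.1102 with an estimated correlation). 9 of 24 fibroblast markers rose and 1 fell, or 10 and 2 adjusted over the list alone. Fibroblast markers were called higher (median 0.17, camera adjusted p = 0.00453, adjusted p = 0.214 with an estimated correlation). COL1A1 had a difference of -0.21 (adjusted p = 0.0562). The fibroblast markers lost their call with only rows in place (adjusted p = 0.299). Exons of ID2 and VIM overlap other genes.

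Lists called lower on day 1 held lipid, pluripotency, replication and mitosis genes. 0 of 28 cholesterol synthesis genes rose and 18 fell, or 0 and 18 adjusted over the list alone, with the fatty acid enzymes SCD and FASN at -0.46 and -0.66. Cholesterol synthesis genes were called lower (median -0.23, camera adjusted p = 2.68e-06, adjusted p = 0.174 with an estimated correlation). 1 of 30 primed and core pluripotency genes rose and 18 fell, or 1 and 18 adjusted over the list alone, with ZFP42, known as REX1 (gene 132625, chromosome 4, 187995771 to 188005050), at 11.7 ± 0.9803 against 36.7 ± 0.222 FPKM. Primed and core pluripotency genes were called lower (median -0.24, camera adjusted p = 2.05e-06, adjusted p = 0.0925 with an estimated correlation). NANOG had a difference of 0.36 (adjusted p = 0.00443), SOX2 one of -0.21 (adjusted p = 0.0409) and POU5F1 one of 0.06 (adjusted p = 0.481). 0 of 38 G1/S and DNA replication genes rose and 9 fell, or 0 and 11 adjusted over the list alone. G1/S and DNA replication genes were called lower (median -0.12, camera adjusted p = 0.00865, adjusted p = 0.3603 with an estimated correlation). 0 of 35 G2/M and mitosis genes rose and 15 fell, or 0 and 16 adjusted over the list alone, with TOP2A, a topoisomerase of dividing cells, at -0.45. G2/M and mitosis genes were called lower (median -0.19, camera adjusted p = 0.000666, adjusted p = 0.0925 with an estimated correlation). DHRS2, a reductase, and HES3, a transcriptional repressor, lay at 2.59 ± 0.549 against 12.9 ± 2.09 FPKM and 1.94 ± 0.571 against 9.598 ± 0.0561 FPKM. CST1 (3.29), a cystatin on an unsettled row, is uncertain. SOX2 also lost its call under median-of-ratios scaling. SOX2 lost its call without D1_Co replicate 2 (adjusted p = 0.101), D1_Co replicate 3 (0.146), D3_Control replicate 2 (0.162) and D3_Control replicate 3 (0.108).

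D2_Co against D3_Control also differs in day. NPPB, a natriuretic peptide precursor (gene 4879, chromosome 1, 11857464 to 11858931), lay at 15.2 ± 1.24 FPKM against 0.731 ± 0.101 FPKM (log2 difference 3.22, SE 0.16, adjusted p = 5.14e-05). TNC, the matrix protein tenascin C (gene 3371, chromosome 9, 115019578 to 115118257), lay at 40.02 ± 10.6 FPKM against 4.72 ± 0.0517 FPKM (log2 difference 2.82, SE 0.16, adjusted p = 9.27e-05). WNT10B reached 8.38 ± 0.182 against 0.2302 ± 0.0293 FPKM, and FGF17 6.697 ± 1.28 against 0.0611 ± 0.0864 FPKM. ZFP42 lay at 5.92 ± 0.133 FPKM against 36.7 ± 0.222 FPKM (log2 difference -2.45, SE 0.06, adjusted p = 6.57e-06). limma called 3117 genes, 1544 higher and 1573 lower, with 249 over 2-fold. The split turned to 1647 higher and 1073 lower with median-of-ratios scaling, 1477 and 1465 with quantile normalization, 1448 and 1230 with no filter, 1531 and 1367 with no trend, 1336 and 1216 with the 4 libraries alone, 1543 and 1538 with unmatched names included and 1287 and 1162 in the table as deposited. It also turned in each fit without 1 library. Without D2_Co replicate 1, D2_Co replicate 3, D3_Control replicate 2 or D3_Control replicate 3, 1902, 1544, 1645 and 1496 genes were called, of which 1061, 906, 1027 and 941 were higher. Without D1_Co replicate 2, D1_Co replicate 3, D3_Co replicate 1 or D3_Co replicate 2, 1451, 1450, 1471 and 1470 were higher and 1442, 1441, 1408 and 1414 lower. Exons of TNC overlap other genes.

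23 of 32 NF-kB targets rose and 0 fell, or 23 and 1 adjusted over the list alone, with NFKBIA, the inhibitor induced by NF-kB, at 23.1 ± 1.21 against 11.3 ± 0.288 FPKM. NF-kB targets were called higher (median 0.73, camera adjusted p = 9.65e-14, adjusted p = 0.0889 with an estimated correlation). 4 of 19 TLR, MyD88 and NF-kB signalling components rose and 0 fell, or 3 and 0 adjusted over the list alone. TLR, MyD88 and NF-kB signalling components were called higher (median 0.12, camera adjusted p = 0.0333, adjusted p = 0.168 with an estimated correlation). MYD88 had a difference of 0.01 (adjusted p = 0.9603). 18 of 22 mesenchymal and EMT genes rose and 0 fell, or 20 and 0 adjusted over the list alone, with CNN1, a calponin, at 91.3 ± 3.93 against 30.2 ± 2.87 FPKM. Mesenchymal and EMT genes were called higher (median 0.60, camera adjusted p = 9.53e-13, adjusted p = 0.0889 with an estimated correlation). Fibroblast markers stood beside them. 13 of 24 fibroblast markers rose and 1 fell, or 15 and 2 adjusted over the list alone, with TAGLN at 221 ± 21.2 against 94.2 ± 5.48 FPKM. Fibroblast markers were called higher (median 0.33, camera adjusted p = 3.85e-06, adjusted p = 0.0889 with an estimated correlation). 13 of 21 YAP and TEAD targets rose and 0 fell, or 15 and 0 adjusted over the list alone, with AXL at 34.2 ± 1.45 against 15.03 ± 0.703 FPKM. YAP and TEAD targets were called higher (median 0.45, camera adjusted p = 3.37e-10, adjusted p = 0.0889 with an estimated correlation). 12 of 25 adhesion, integrin and basement membrane genes rose and 2 fell, or 12 and 2 adjusted over the list alone, with ITGAV at 32.8 ± 1.49 against 13.1 ± 1.34 FPKM. Adhesion, integrin and basement membrane genes were called higher (median 0.16, camera adjusted p = 8.17e-06, adjusted p = 0.0889 with an estimated correlation). 5 of 7 mesendoderm and endoderm genes rose and 0 fell, or 5 and 1 adjusted over the list alone, with CER1 at 253 ± 15.4 against 44.9 ± 5.21 FPKM. Mesendoderm and endoderm genes were called higher (median 1.02, camera adjusted p = 0.00117, adjusted p = 0.0901 with an estimated correlation). 10 of 19 NODAL and activin targets rose and 3 fell, or 12 and 4 adjusted over the list alone. NODAL and activin targets were called higher (median 0.52, camera adjusted p = 0.00404, adjusted p = 0.168 with an estimated correlation). TLR, MyD88 and NF-kB signalling components lost their call without D2_Co replicate 1 (adjusted p = 0.06395) and D3_Control replicate 3 (0.05201) and with a mean of at least 5 FPKM (0.266), quantile normalization (0.0522), another reference (0.0538) and only rows in place (0.05298). The mesendoderm and endoderm genes lost their call with only rows in place (adjusted p = 0.0518). The NODAL and activin targets lost their call with only rows in place (adjusted p = 0.161). Exons of AXL and TAGLN overlap other genes.

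Lists called lower on day 2 held growth, cell cycle, pluripotency, chaperone and respiration genes. 0 of 38 MYC targets and ribosome biogenesis genes rose and 24 fell, or 0 and 28 adjusted over the list alone. MYC targets and ribosome biogenesis genes were called lower (median -0.24, camera adjusted p = 2.3e-08, adjusted p = 0.0889 with an estimated correlation). 0 of 45 cytosolic ribosomal protein genes rose and 2 fell, or 0 and 0 adjusted over the list alone. Cytosolic ribosomal protein genes were called lower (median -0.11, camera adjusted p = 0.0175, adjusted p = 0.3898 with an estimated correlation). 0 of 38 G1/S and DNA replication genes rose and 17 fell, or 1 and 18 adjusted over the list alone. G1/S and DNA replication genes were called lower (median -0.20, camera adjusted p = 0.0005701, adjusted p = 0.248 with an estimated correlation). 0 of 35 G2/M and mitosis genes rose and 8 fell, or 0 and 11 adjusted over the list alone. G2/M and mitosis genes were called lower (median -0.11, camera adjusted p = 0.0129, adjusted p = 0.0901 with an estimated correlation). 1 of 30 primed and core pluripotency genes rose and 16 fell, or 1 and 18 adjusted over the list alone. Primed and core pluripotency genes were called lower (median -0.22, camera adjusted p = 3.5e-05, adjusted p = 0.0889 with an estimated correlation). 2 of 17 heat shock genes rose and 12 fell, or 2 and 12 adjusted over the list alone, with FKBP4, a co-chaperone, at -0.50. Heat shock genes were called lower (median -0.30, camera adjusted p = 0.00114, adjusted p = 0.168 with an estimated correlation). 0 of 42 nuclear-encoded oxidative phosphorylation genes rose and 18 fell, or 0 and 18 adjusted over the list alone, with COX8A at -0.28. Nuclear-encoded oxidative phosphorylation genes were called lower (median -0.16, camera adjusted p = 0.000118, adjusted p = 0.0889 with an estimated correlation). ANKRD1 (3.07), on an unsettled row, is uncertain. Cytosolic ribosomal protein genes lost their call without D2_Co replicate 1 (adjusted p = 0.148) and with a mean of at least 5 FPKM (0.0548) and median-of-ratios scaling (0.0508). The G2/M and mitosis genes lost their call with quantile normalization (adjusted p = 0.109) and only rows in place (0.0518). Exons of COX8A and FKBP4 overlap other genes.

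**Figure D2:**
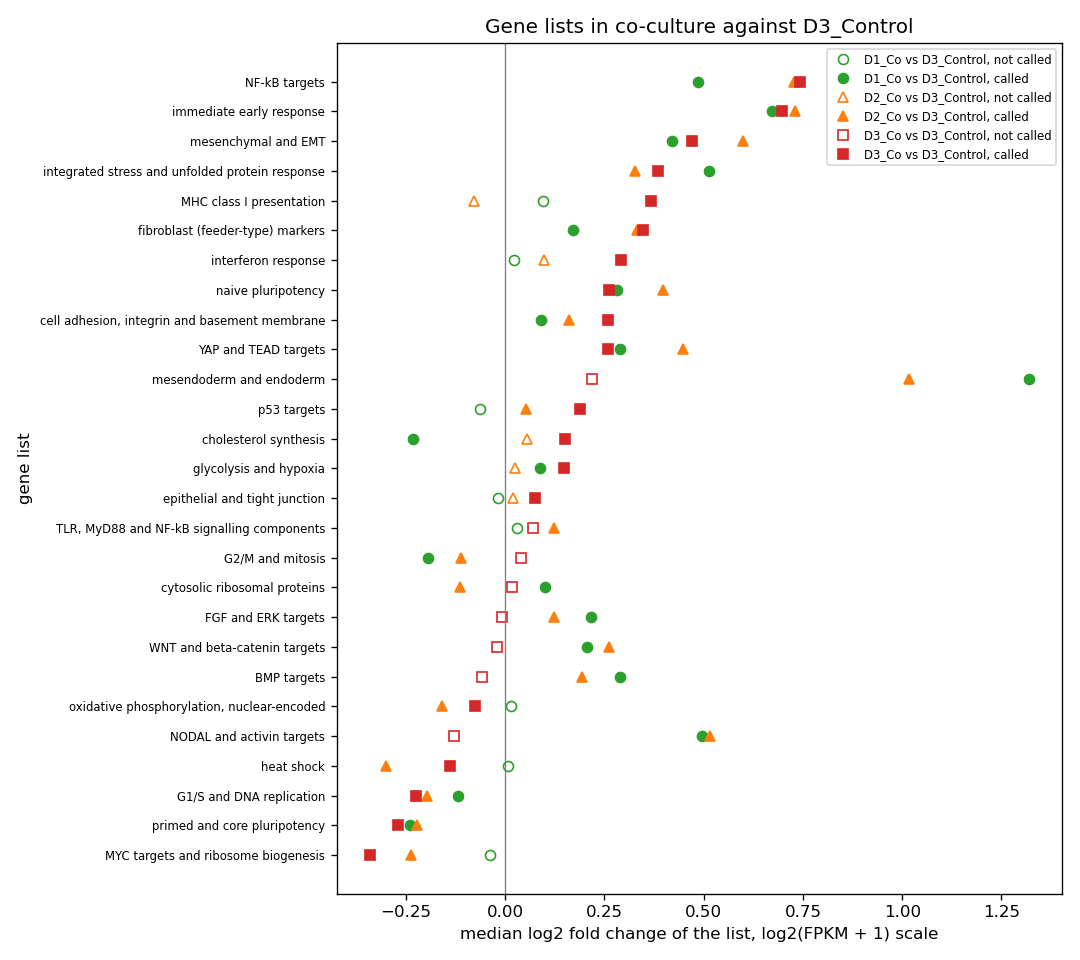
Median log2 difference over the measured genes (horizontal axis, log2(FPKM + 1) scale) of each gene list called in at least 1 comparison with D3_Control (vertical axis), for D1_Co, D2_Co and D3_Co, where filled points passed camera and open points did not. The median of the NF-kB targets lies at 0.49, 0.73 and 0.74 on days 1, 2 and 3, and that of the mesendoderm and endoderm genes at 1.32, 1.02 and 0.22.

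Calls made against D3_Control on all 3 days in the same direction numbered 1019 genes, 675 higher and 344 lower. D1_Co and D3_Co shared 1202, D2_Co and D3_Co 1585, and D1_Co and D2_Co 1736. Independent lists of these lengths share 342, 379 and 355. In 100 simulations of unchanged groups each pair shared 1 gene at most. With no gene changed, this is no yardstick. The fold changes of these pairs correlated across genes at 0.568, 0.668 and 0.754, beside 0.497, 0.499 and 0.499 in these simulations, where only the controls are shared. Their covariances were 0.0626, 0.0748 and 0.0929 beside 0.0082 simulated from the shared controls alone. With the controls split, 1 library to each comparison of a pair in both ways, the pairs correlated at 0.401 and 0.474, 0.521 and 0.539, and 0.593 and 0.652, with covariances of 0.0493 and 0.0557, 0.0639 and 0.0655, and 0.0804 and 0.0852. They then shared 562 and 581, 667 and 709, and 843 and 839 genes. A single library is a poor control, and part of the excess may come from the controls. Without D3_Co replicate 2, D3_Control replicate 2 or D3_Control replicate 3 the overlap was 676, 616 and 516 genes.

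D2_Co against D1_Co asks what moved from day 1 to day 2 of co-culture. ACTG2, an actin (gene 72, chromosome 2, 73892314 to 73919865), rose to 88.8 ± 3.903 FPKM against 19.01 ± 3.23 FPKM (log2 difference 2.17, SE 0.14, adjusted p = 0.00144), and ACTC1, another actin (gene 70, chromosome 15, 34788095 to 34795726), to 18.8 ± 1.43 against 3.74 ± 0.306 FPKM. Actin genes share sequence, so their split among members is uncertain. EOMES lay at 1.295 ± 0.433 against 3.89 ± 0.315 FPKM. limma called 883 genes, 526 higher and 357 lower, with 46 over 2-fold. The count fell to 344 genes with no filter and to 154 with the 4 libraries alone. Leaving out D1_Co replicate 2, D1_Co replicate 3, D2_Co replicate 1, D2_Co replicate 3, D3_Control replicate 2 or D3_Control replicate 3 left 160, 113, 85, 67, 459 and 457. EOMES lost its call without D1_Co replicate 2 (adjusted p = 0.0531), D1_Co replicate 3 (0.06596) and D2_Co replicate 1 (0.0619). Exons of ACTC1 overlap other genes.

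17 of 28 cholesterol synthesis genes rose and 1 fell, or 27 and 1 adjusted over the list alone, with INSIG1, a sterol sensor, at 31.6 ± 0.515 against 19.7 ± 0.0903 FPKM. Cholesterol synthesis genes were called higher (median 0.35, camera adjusted p = 1.82e-12, adjusted p = 0.2096 with an estimated correlation). 0 of 45 cytosolic ribosomal protein genes rose and 6 fell, or 0 and 23 adjusted over the list alone. Cytosolic ribosomal protein genes were called lower (median -0.21, camera adjusted p = 6.71e-11, adjusted p = 0.2096 with an estimated correlation). 0 of 38 MYC targets and ribosome biogenesis genes rose and 11 fell, or 0 and 23 adjusted over the list alone. MYC targets and ribosome biogenesis genes were called lower (median -0.20, camera adjusted p = 4.28e-10, adjusted p = 0.0601 with an estimated correlation). 1 of 33 integrated stress and unfolded protein response genes rose and 9 fell, or 1 and 12 adjusted over the list alone. Integrated stress and unfolded protein response genes were called lower (median -0.14, camera adjusted p = 6.49e-06, adjusted p = 0.2096 with an estimated correlation). 0 of 7 mesendoderm and endoderm genes rose and 3 fell, or 0 and 3 adjusted over the list alone. Mesendoderm and endoderm genes were called lower (median -0.33, camera adjusted p = 0.00264, adjusted p = 0.2096 with an estimated correlation). 9 of 32 NF-kB targets rose and 0 fell, or 12 and 1 adjusted over the list alone, with IL32 at 15.7 ± 1.44 against 5.94 ± 1.62 FPKM. NF-kB targets were called higher (median 0.18, camera adjusted p = 0.00264, adjusted p = 0.299 with an estimated correlation). Fibroblast markers were higher as well. 7 of 24 fibroblast markers rose and 1 fell, or 11 and 1 adjusted over the list alone. Fibroblast markers were called higher (median 0.15, camera adjusted p = 0.00165, adjusted p = 0.2804 with an estimated correlation). NANOG had a difference of -0.43 (adjusted p = 0.0137). IL32 lost its call without D2_Co replicate 3 (adjusted p = 0.0641). NANOG lost its call without D1_Co replicate 2 (adjusted p = 0.0586), D1_Co replicate 3 (0.0593), D2_Co replicate 1 (0.0707) and D2_Co replicate 3 (0.0724). The NF-kB targets lost their call with a mean of at least 5 FPKM (adjusted p = 0.305) and only rows in place (0.127).

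D3_Co against D2_Co follows the next day. ZFP42 rose again, to 30.5 ± 0.457 FPKM against 5.92 ± 0.133 FPKM (log2 difference 2.19, SE 0.06, adjusted p = 4.39e-05). FGF17 fell to 0.0372 ± 0.0526 against 6.697 ± 1.28 FPKM, and IGFBP5, a carrier of insulin-like growth factors (gene 3488, chromosome 2, 216672105 to 216695525), to 1.57 ± 0.0575 against 7.94 ± 0.222 FPKM. CBR1, a carbonyl reductase (gene 873, chromosome 21, 36069941 to 36073166), rose to 26.02 ± 1.10 against 6.96 ± 0.346 FPKM, and LNCPRESS1, a long non-coding RNA (gene 101927721, chromosome 7, 101299578 to 101301346), to 4.64 ± 0.396 against 0.7403 ± 0.0708 FPKM. limma called 1984 genes, 1086 higher and 898 lower, with 66 over 2-fold, and the fit with the 4 libraries alone called 1033. The split turned to 697 higher and 1249 lower with median-of-ratios scaling and to 989 and 1030 with quantile normalization. Without D2_Co replicate 1, D2_Co replicate 3, D3_Co replicate 1 or D3_Co replicate 2, 560, 480, 475 and 665 genes were called, with the split turned in the last 2 fits (233 higher and 242 lower, 304 and 361), and the lists called fell from 14 to 9 without D2_Co replicate 1. Exons of CBR1 and IGFBP5 overlap other genes.

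1 of 19 NODAL and activin targets rose and 12 fell, or 1 and 13 adjusted over the list alone, with LEFTY2, a NODAL antagonist, at 11.1 ± 0.481 against 32.9 ± 3.29 FPKM. NODAL and activin targets were called lower (median -0.34, camera adjusted p = 1.07e-06, adjusted p = 0.138 with an estimated correlation). 1 of 7 mesendoderm and endoderm genes rose and 6 fell, or 1 and 6 adjusted over the list alone. Mesendoderm and endoderm genes were called lower (median -0.99, camera adjusted p = 0.000255, adjusted p = 0.138 with an estimated correlation). 0 of 21 YAP and TEAD targets rose and 9 fell, or 0 and 12 adjusted over the list alone, with IGFBP3 at -1.05. YAP and TEAD targets were called lower (median -0.21, camera adjusted p = 1.07e-06, adjusted p = 0.138 with an estimated correlation). 0 of 9 BMP targets rose and 4 fell, or 0 and 4 adjusted over the list alone, with ID1 at -0.82. BMP targets were called lower (median -0.27, camera adjusted p = 0.0005098, adjusted p = 0.234 with an estimated correlation). 7 of 15 MHC class I genes rose and 0 fell, or 7 and 0 adjusted over the list alone. MHC class I genes were called higher (median 0.21, camera adjusted p = 0.000192, adjusted p = 0.138 with an estimated correlation). 8 of 35 p53 targets rose and 3 fell, or 19 and 3 adjusted over the list alone, with GDF15 at 35.2 ± 1.83 against 18.8 ± 2.25 FPKM. The p53 targets were called higher (median 0.19, camera adjusted p = 0.00193, adjusted p = 0.268 with an estimated correlation). 12 of 35 G2/M and mitosis genes rose and 0 fell, or 12 and 0 adjusted over the list alone, with TOP2A at 62.5 ± 0.909 against 42.2 ± 0.0834 FPKM. G2/M and mitosis genes were called higher (median 0.14, camera adjusted p = 0.003898, adjusted p = 0.138 with an estimated correlation). EMP1 (-1.87) and CST1 (-1.74) lie on unsettled rows and are uncertain. The p53 targets lost their call with only rows in place (adjusted p = 0.0619). Exons of LEFTY2 overlap other genes.

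D3_Co against D1_Co spans the co-culture days. FGF17 fell to 0.0372 ± 0.0526 against 6.41 ± 0.718 FPKM, SP5 to 0.7999 ± 0.151 against 7.14 ± 0.654 FPKM and CER1 to 98.9 ± 2.02 FPKM against 343 ± 33.1 FPKM (log2 difference -1.78, SE 0.10, adjusted p = 0.000348). MALAT1, a nuclear long non-coding RNA, lay at 17.4 ± 6.57 against 4.73 ± 0.267 FPKM, and LTB, lymphotoxin beta, at 3.12 ± 1.12 against 0.326 ± 0.174 FPKM. HES3 rose to 7.11 ± 0.4197 against 1.94 ± 0.571 FPKM. limma called 3310 genes, 2003 higher and 1307 lower, with 88 over 2-fold. Median-of-ratios scaling turned the split to 1474 higher and 2105 lower. Without D1_Co replicate 2, D1_Co replicate 3, D3_Co replicate 1 or D3_Co replicate 2, 1864, 1810, 2017 and 1673 genes were called. Exons of MALAT1 overlap other genes.

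22 of 28 cholesterol synthesis genes rose and 0 fell, or 24 and 0 adjusted over the list alone, with SCD at 515 ± 13.5 against 356 ± 2.45 FPKM. Cholesterol synthesis genes were called higher (median 0.42, camera adjusted p = 2.76e-09, adjusted p = 0.141 with an estimated correlation). 1 of 7 mesendoderm and endoderm genes rose and 6 fell, or 1 and 6 adjusted over the list alone. Mesendoderm and endoderm genes were called lower (median -1.28, camera adjusted p = 4.17e-05, adjusted p = 0.134 with an estimated correlation). 1 of 38 MYC targets and ribosome biogenesis genes rose and 23 fell, or 1 and 26 adjusted over the list alone, with ODC1, the rate-limiting enzyme of polyamine synthesis, at 131 ± 7.93 against 209 ± 6.37 FPKM. MYC targets and ribosome biogenesis genes were called lower (median -0.27, camera adjusted p = 1.56e-09, adjusted p = 0.119 with an estimated correlation). 0 of 9 BMP targets rose and 7 fell, or 1 and 7 adjusted over the list alone, with GREM1, a BMP antagonist, at 3.16 ± 0.116 against 10.9 ± 1.91 FPKM. BMP targets were called lower (median -0.53, camera adjusted p = 6.08e-05, adjusted p = 0.141 with an estimated correlation). 16 of 35 p53 targets rose and 1 fell, or 18 and 3 adjusted over the list alone, with DDB2, a DNA damage sensor, at 41.5 ± 4.797 against 21.4 ± 0.421 FPKM. The p53 targets were called higher (median 0.29, camera adjusted p = 0.000352, adjusted p = 0.212 with an estimated correlation). 14 of 35 G2/M and mitosis genes rose and 0 fell, or 15 and 0 adjusted over the list alone, with BUB1B, a spindle checkpoint kinase, at 37.7 ± 0.333 against 26.4 ± 1.15 FPKM. G2/M and mitosis genes were called higher (median 0.22, camera adjusted p = 0.0008701, adjusted p = 0.134 with an estimated correlation). COL1A1 had a difference of 0.75 (adjusted p = 0.00125), beside MYD88 at -0.20 (adjusted p = 0.0481). MYD88 lost its call without D1_Co replicate 2 (adjusted p = 0.158), D1_Co replicate 3 (0.1199), D2_Co replicate 1 (0.0581), D2_Co replicate 3 (0.0578), D3_Co replicate 1 (0.184), D3_Co replicate 2 (0.0813), D3_Control replicate 2 (0.0704) and D3_Control replicate 3 (0.0701). Exons of BUB1B and GREM1 overlap other genes.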

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

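In this part the tests of fibroblast transcripts, mouse reads, summed metallothioneins, pluripotency genes, days since plating and misplaced values on day 2 were chosen only after the result was seen, while the other tests of misplaced values and that of SLC39A10 were set before. Each list and gene of the next 2 paragraphs drew attention because the difference from D3_Control on day 3 differed from that on day 1, tested by limma or camera as D3_Co against D1_Co, in which the shared control cancels. Values are differences of log2 effects, day 3 minus day 1, and for lists the median over genes of these differences. Of the patterns weighed after them, that of NODAL and mesendoderm genes came from this test, the metallothioneins were chosen after their values were seen, and NF-kB targets, chosen for their rise in co-culture, were not called by camera between D3_Co and D1_Co (adjusted p = 0.214).

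Among gene lists, medians lay higher on day 3 for p53 targets by 0.29 (0.19 on day 3, -0.06 on day 1), G2/M and mitosis by 0.22 (0.04 on day 3, -0.19 on day 1), interferon response by 0.20 (0.29 on day 3, 0.02 on day 1), MHC class I presentation by 0.26 (0.37 on day 3, 0.10 on day 1), cholesterol synthesis by 0.42 (0.15 on day 3, -0.23 on day 1) and epithelial and tight junction by 0.12 (0.07 on day 3, -0.02 on day 1). They lay lower for MYC targets and ribosome biogenesis, -0.27, G1/S and DNA replication, -0.0926, oxidative phosphorylation, -0.10, the integrated stress and unfolded protein response, -0.17, heat shock, -0.13, YAP and TEAD targets, -0.0810, BMP targets, -0.53 (-0.06 on day 3, 0.29 on day 1), FGF and ERK targets, -0.11, NODAL and activin targets, -0.47 (-0.13 on day 3, 0.49 on day 1), and mesendoderm and endoderm, -1.28 (0.22 on day 3, 1.32 on day 1). Cytosolic ribosomal proteins lay lower by -0.0869, a list that fry did not call (adjusted p = 0.0999). Epithelial and tight junction genes lost this call with median-of-ratios scaling (camera adjusted p = 0.0884), the 4 libraries alone (0.0629), only rows in place (0.0663), without D1_Co replicate 3 (0.0653), without D3_Co replicate 1 (0.151), without D3_Control replicate 2 (0.0672) and without D3_Control replicate 3 (0.0672). Interferon-response genes lost this call with quantile normalization (camera adjusted p = 0.0863), only rows in place (0.0525) and without D1_Co replicate 3 (0.0647). Heat shock genes lost this call with quantile normalization (camera adjusted p = 0.267), only rows in place (0.108) and without D3_Co replicate 2 (0.0647). YAP and TEAD targets lost this call with only rows in place (camera adjusted p = 0.0525). Nuclear-encoded oxidative phosphorylation genes lost this call with quantile normalization (camera adjusted p = 0.401). Cytosolic ribosomal protein genes lost this call with a mean of at least 5 FPKM (camera adjusted p = 0.05602), quantile normalization, which turned the direction (0.868) and without D3_Co replicate 2 (0.166). None of these lists was called with an estimated correlation.

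Among named genes, D3_Co lay above D1_Co for GARIN1B, 0.42, CH25H, 0.40, IL32, 1.34, ZC3H12A, 0.79, CXCL1, 1.10, PIK3CD, 0.47, MDM2, 0.40, and COL1A1, 0.75. It did so for MT1E, 0.71, MT1G, 1.36, DHRS2, 1.03, and HES3, 1.47, with smaller day 3 falls. It lay lower for WNT10B, -0.36, NANOG, -0.47, MYC, -0.42, CER1, -1.78, FGF17, -2.83, SP5, -2.18, and unsettled CST1, -2.70. Day 3 falls were larger for IQSEC2, -0.32, COX11, -1.40, MYD88, -0.20 (call lost in each fit without 1 library), and unsettled SFRP1, -0.29.

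NF-kB targets were higher in co-culture on all 3 days. Misplaced values are argued against as the whole cause. The 21 of 32 targets whose values stood in place had a median log2 difference of 0.64 on day 3. Mouse reads stay open, as no mouse genome was used here. IL32 and CXCL8, genes that mice lack, rose by at least 1.58, but this test was narrowed to them after its value was seen. Fibroblast-type cells rich in COL3A1, DCN, LUM and POSTN stay open. With spread, the summed difference of these 4 in D3_Co, 0.124 ± 0.259 FPKM, is a share of 0.00156 of the 245 FPKM by which the 32 targets rose. PLAU held 102 of these, and the median target rise was 2.25. POSTN reached 0.992 FPKM in a D3_Co library, not clear of a bound of 1 with its spread of 0.257. The share and the largest rise of the 4 genes, 0.149 FPKM, were chosen after that result and do not decide. Fibroblast-type cells poor in these 4 stay open, as 14 of 24 fibroblast markers rose and 1 fell. Mouse reads cannot be told apart from human ones for the other 30 targets because no mouse genome was used here, and a response of the human cells to co-culture remains an untested hypothesis.

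Metallothioneins were lower in co-culture than in D3_Control. Misplaced values are argued against as the whole cause, since the 3 of 7 members that stood in place had a median of -0.98 on day 3. Reads shifted among the 7 measured copies are argued against as the whole cause. Their sum was 193 ± 5.07 FPKM in D3_Co and 417 ± 27.3 FPKM in D3_Control, a log2 ratio of -1.11. The fall of the single members was known before this sum was taken. Copies on rows left out of the test are not in the sum, so reads shifted to them stay open. Less available zinc, which may lower these genes, stays open, since SLC39A10, an importer repressed by zinc, had a difference of 0.19 (limma adjusted p = 0.104) on day 3 and of -0.20 on day 1, while SLC30A1, an exporter induced by zinc, was lower by a log2 difference of -1.05. The medium of each library is not given in the sources used here, so a difference of medium is open and untested.

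NODAL targets and mesendoderm genes were high on days 1 and 2 of co-culture and lower on day 3. For the fall from day 1 to day 3, misplaced values are argued against as the whole cause. The 15 of 22 genes that stood in place had a median log2 difference of -0.42 between D3_Co and D1_Co. Misplaced values stay open for the height on day 2, where these genes had a median of 0.19. With only rows in place neither list was called on day 2 (NODAL and activin targets, camera adjusted p = 0.161, mesendoderm and endoderm, 0.0518). Loss of the pluripotent state on day 1 stays open, since of POU5F1, SOX2 and NANOG only SOX2, 1 gene, was called lower in D1_Co and NANOG was higher, while the primed and core pluripotency list was called lower (camera adjusted p = 2.05e-06, adjusted p = 0.0925 with an estimated correlation). Days since plating and co-culture cannot be told apart, because 2 of the co-culture days have no separate-culture libraries of that day. A passing response to the partner cells remains an untested hypothesis.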

How the results depend on the processing

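The alternatives on the realigned rows, another reference and unmatched names were chosen only after the data were seen, as was the table as deposited, and the others before. Among the 532 results for named genes and the alternatives run for them, which leave out the table as deposited and at least 2-fold, 795 calls were lost, 28 gained and 0 turned, and for the 198 list results 115 were lost, 39 gained and 2 turned, besides the estimated correlation, with which every list call was lost. Cytosolic ribosomal proteins changed sign and lost their call with quantile normalization in D1_Co against D3_Control (camera adjusted p = 1.00) and in D3_Co against D1_Co (0.868), and the cause was not tested. Where neither value was called, a change of sign was not counted. Asking for at least 2-fold left 150, 228, 249, 46, 66 and 88 genes in D3_Co, D1_Co and D2_Co against D3_Control, D2_Co against D1_Co, D3_Co against D2_Co and D3_Co against D1_Co, and an estimated correlation left 0 lists in each. No filter called 344 genes in D2_Co against D1_Co, where more genes are adjusted for, and the fit of the 4 libraries alone called 154 there and 1033 in D3_Co against D2_Co, with fewer samples. Only rows in place in all libraries, fewer genes, gave 1877, 1753, 1982, 545, 1218 and 2030 genes in the same order, an overlap of 624, and 9 lists in D3_Co against D2_Co. The table as deposited, whose values partly belong to other genes, gave 12, 12, 11, 7, 4 and 11 lists and a mean within-group correlation of 0.830, against 0.988 with a pseudocount of 0.1 and 0.996 with no filter. Leaving out each library in turn, with a lone sample assumed to vary like the other groups, gave 1603 to 2845, 1355 to 2611, 1496 to 2893, 67 to 667, 475 to 1680 and 1673 to 3009 genes, 9 to 14 lists in D3_Co against D2_Co and an overlap of 516 to 831. The replicate numbers do not pair the samples, as deviations of same-numbered libraries correlated between -0.031 and 0.044. With the number as a replicate block, 1819 genes were called in D3_Co against D3_Control, 2076 in D2_Co against D3_Control, 101 in D2_Co against D1_Co, 720 in D3_Co against D2_Co and 1934 in D3_Co against D1_Co, and the split of D2_Co against D3_Control turned to 1170 higher and 906 lower. List calls lost with the block were oxidative phosphorylation, nuclear-encoded in D3_Co against D3_Control (camera adjusted p = 0.0781), epithelial and tight junction in D3_Co against D3_Control (0.0820), p53 targets in D2_Co against D3_Control (0.0577), cell adhesion, integrin and basement membrane in D2_Co against D1_Co (0.0562), MYC targets and ribosome biogenesis in D3_Co against D2_Co (0.05997), oxidative phosphorylation, nuclear-encoded in D3_Co against D2_Co (0.0509) and epithelial and tight junction in D3_Co against D1_Co (0.118). Groups of 2 are too small for a test of outlying samples or of other splits, the table lists genes and not transcripts, and unknown depth limits what can be said of low genes.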

Other observations

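The metallothionein family and the genes below were chosen after their values were seen. All 7 measured members, MT1E, MT1F, MT1G, MT1H, MT1M, MT1X and MT2A, were called lower on days 1 and 2 of co-culture against D3_Control (median log2 differences -1.84 and -1.56), and 6 of 7 on day 3 (median -1.08), with MT1M at -0.81 (limma adjusted p = 0.0734). The summed family rose over the co-culture days, from 110 ± 11.5 FPKM on day 1 to 149 ± 1.03 on day 2 and 193 ± 5.07 on day 3, still below the 417 ± 27.3 of D3_Control, and 6 of 7 members were called higher in D3_Co than in D1_Co. SLC30A1, a zinc exporter, was lower on all 3 days, by log2 differences of -0.75, -0.43 and -1.05. HMOX1, heme oxygenase, lay at 36.6 ± 2.37 FPKM on day 1, 23.0 ± 0.773 on day 2 and 20.7 ± 2.39 on day 3 against 37.8 ± 0.919 in D3_Control, and was called lower on days 2 and 3.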
